A study of Mus musculus with 4 samples.

How the data were processed

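Droplet-based 5-prime single-cell RNA sequencing and the matching T and B cell receptor libraries were analysed from CD45-positive heart cells of Balb/c mice. Their age is given as 6 to 8 weeks for every group, day 60 included, so it is not the age at collection throughout. Age at collection cannot be separated from day. Per the labels, the 4 groups were a normal control (day 0) and the acute (day 14), subacute (day 21) and myopathy phases (day 60) of experimental autoimmune myocarditis, raised with 250 micrograms of a cardiac myosin peptide in adjuvant on days 0 and 7. Each group was 1 library, so no group had replicates.

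The deposited expression matrices hold counts, meaning whole-number UMIs per gene and barcode, which the authors made with Cell Ranger 2.2 on mm10 per the submitters' processing notes. The deposited receptor tables give, per the file headers, a fraction, in the columns with the proportion of each clonotype, and cell counts per clonotype. Other deposited columns, of the type "other", hold barcodes, gene identifiers and symbols. The authors also deposited a merged table of the cells they kept (6888, 10351, 10821 and 6605 on days 0, 14, 21 and 60), which served here as an alternative set of cells. Details of the alignment beyond these were not given in the sources used here.

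The matrices held 7059, 10651, 11240 and 6978 barcodes and 28692 genes, with 62077026, 145922109, 136857665 and 81477074 UMIs, medians of 7660, 12070, 10194 and 9550 UMIs and 2122, 2778, 2509 and 2426.5 genes per barcode. Barcodes with fewer than 200 genes or over 10% mitochondrial UMIs were removed (17, 11, 35 and 15). Doublets were scored with Scrublet in scanpy 1.11.5 (30 principal components, 0.8% expected doublets per 1000 barcodes) and removed above a score of 0.25 (127, 638, 664 and 94 barcodes). That threshold was set after seeing the data, because the automatic one removed 0.0850% and 0% of barcodes on days 0 and 60 against 5.51% and 4.48% on days 14 and 21. This left 6915, 10002, 10541 and 6869 cells.

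Counts were scaled to a total of 10000 per cell and log-transformed. From 2000 variable genes without immunoglobulin and receptor genes, 40 principal components and 20 neighbours per cell were used for Leiden clustering (leidenalg 0.10.2, igraph 0.11.9, resolution 2), which gave 49 clusters over the 4 libraries together. No batch correction was applied, since it could remove differences between days. Clusters were named from marker lists: a marker counted when detected in 20% of cells, a name needed at least 3 detected markers and a score of at least 0.6, and a second lineage with at least 3 detected markers and a score of at least 0.58 made a cluster mixed. For that rule B and plasma cells were 1 lineage, T, NK and ILC2 cells were 1, and cDC2 counted with phagocytes; clusters named DC were not called mixed with phagocytes when their macrophage score was below 0.58. T subsets needed a score of at least 0.85 and a lead of 0.1. The names therefore mean resemblance to markers, and Treg-like and gamma-delta T-like cells were 1 cluster each. These thresholds, the mixing rule and the thymocyte list were chosen after the clusters had been seen.

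A further check asked whether a cluster's 10 leading genes held markers of its type. It was run in 4 versions, and the strictest, which was run before the others, decided. It left clusters 4, 11, 16 and 27 unnamed although macrophage was their best score; the 3 looser versions were tried after these clusters had failed and were not used. Cluster 4 held 0.217%, 10.5%, 7.75% and 0.335% of the cells on days 0, 14, 21 and 60, cluster 11 held 1.56%, 1.70%, 4.15% and 5.55%, cluster 16 held 0.434%, 2.82%, 4.95% and 0.146%, and cluster 27 held 1.95%, 1.06%, 0.949% and 0.903%. Another 9 clusters were mixed and cluster 40 held thymocyte genes, so 14 of 49 clusters and 9.07%, 18.5%, 24.8% and 14.3% of the cells stayed unnamed.

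Expression was compared on counts summed per class and library, with counts scaled by the class total (CPM), for classes of at least 50 cells. With 1 library per day no test between days was run. Ratios carry exact 95% conditional binomial intervals, shares Clopper-Pearson intervals and CPM exact Poisson intervals, all for counting error only. Where a gene had 0 UMIs on 1 side, the ratio is a bound against a floor of 3 UMIs over the class. Where 0 cells held a UMI, the limit given is 3 divided by the number of cells and not a Clopper-Pearson bound. A gene was named when it had at least 30 UMIs and 100 CPM on 1 side, at least 10% of the CPM of its highest class (against RNA free in the suspension), and an interval beyond 2-fold. Ranked by the interval bound nearest 1, up to 8 of the highest and 6 of the lowest were taken for phagocyte-like and T-like cells against day 0, and up to 5 and 4 otherwise. Up to 4 members per list and a set of genes fixed in advance were added, and the report gives part of the list members. A few genes taken by these rules were not used here.

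The 29 gene lists cover interferon responses, antigen presentation, metabolism, macrophage, T, B and neutrophil programmes, the cell cycle, glucocorticoid response, heat shock and dissociation stress, and sex-linked transcripts; 4 of their genes were absent from the matrices. Members with at least 10 UMIs over both libraries entered the median, which was placed among 10000 random lists matched over 20 expression bins. Because a cell's depth sets how often a transcript is seen, shares of cells with a UMI were computed after thinning each cell to 1000 UMIs, which left out 0 cells.

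Receptor barcodes were joined to the matrices: 642, 1279, 1811 and 852 of 760, 1588, 2757 and 1275 barcodes with a T cell receptor, and 630, 496, 472 and 631 of 786, 647, 729 and 877 with a B cell receptor, were found there. Kept T-like cells with a clonotype were 363, 754, 992 and 339. Clonotypes are those of the authors' tables, and equal numbers of cells (339) were drawn 1000 times. Subset names were rebuilt here, as the labels give none.

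The summed-count ratios were run on simulated data made from the day 14 and day 0 libraries. Counts were Poisson draws around their averaged profile, without spread between cells or libraries. The simulation checked the calculation only, since interval coverage near 95% follows from such draws. Of 100 planted 2-fold differences, 96 were recovered in phagocyte-like and 92 in T-like cells, and of 100 planted 4-fold differences 100 and 99; the intervals held the true ratio for 95.3% and 96.0% of genes, and 194 and 196 of 200 unaltered lists lay inside their 95% range.

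The comparisons, the gene lists and 13 alternatives were fixed before the data were examined; these cover cell filtering, doublets, clustering per library, scaling by trimmed mean of M values (TMM, own implementation), the count minimum for list members, thinning and the definition of clonotypes. Another 13 alternatives were added after seeing the data: the 4 unnamed macrophage clusters counted as phagocyte-like, cluster 40 counted as T-like, the authors' cells, 1 UMI minimum of 3945 for all libraries, equal cell numbers, and leaving out the largest clonotype. The list alternatives were run for phagocyte-like and T-like cells and not for neutrophil-like, B-like, NK-like and DC-like cells. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9. Embeddings, trajectories and cell-to-cell signalling were not analysed here, and raw reads were not used here.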

Results

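CD45-positive cells sorted from the hearts of Balb/c mice were compared between a normal control (day 0) and days 14, 21 and 60 of autoimmune myocarditis raised with a cardiac myosin peptide. Each day is 1 library, so there are no replicates, day and library cannot be told apart, and all intervals are 95% and cover counting error only. Types carry the ending -like because they were assigned here from marker genes. A gene list is described by the median log2 ratio of its members, and its members count as higher or lower at 1.5-fold. Unless a percentile is given, a list's median in the named classes lay below the 0.5th or above the 99.5th percentile of random lists of similarly expressed genes. Medians from alternative settings carry no such statement unless a percentile is given. Where a gene had 1 to 3 UMIs on 1 side, that number stands beside its ratio.

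Phagocyte-like cells, meaning macrophages and monocytes, made up 67.1% (66.0 to 68.2) of the kept cells in the day 0 library and 45.3% (44.3 to 46.2), 41.3% (40.4 to 42.3) and 49.3% (48.1 to 50.5) in the day 14, 21 and 60 libraries. Neutrophil-like cells were 1.85% (1.55 to 2.2) on day 0, 19.0% (18.2 to 19.7) on day 14, 15.6% (14.9 to 16.3) on day 21 and 6.16% (5.6 to 6.75) on day 60. T-like cells, the lymphocytes that carry the autoimmune response in this model, were 6.07% (5.52 to 6.66), 8.36% (7.82 to 8.92), 10.2% (9.62 to 10.8) and 7.80% (7.18 to 8.46). B-like cells were lower in the day 14 library, at 0.640% (0.493 to 0.816), and in the day 21 library, at 1.40% (1.19 to 1.65), than on day 0 (5.55%, 5.02 to 6.12) or day 60 (5.36%, 4.84 to 5.92). Dendritic (DC)-like cells were 5.21% (4.69 to 5.76), 4.06% (3.68 to 4.46), 3.94% (3.57 to 4.33) and 11.7% (10.9 to 12.5), and ILC2-like cells, innate lymphocytes of type 2, were 2.21% (1.88 to 2.59), 0.260% (0.170 to 0.381), 0.0759% (0.0328 to 0.149) and 1.14% (0.899 to 1.42). These are shares of CD45-sorted cells and sum to 100%, and the lowest UMI count that the authors' cell calling passed differed between libraries (2670, 3945, 3715 and 3629). Clusters without a name held 9.07%, 18.5%, 24.8% and 14.3% of the cells. With 1 UMI minimum for all libraries, day 0 held 2.34% B-like and 0.429% neutrophil-like cells. With clusters found in each library separately, phagocyte-like cells were 47.2%, 36.7%, 52.8% and 50.3% and unnamed cells 29.2%, 26.2%, 12.4% and 14.7%, so day 0 then lay below days 21 and 60, and B-like cells on day 21 were 2.18%.

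**Figure D1:**
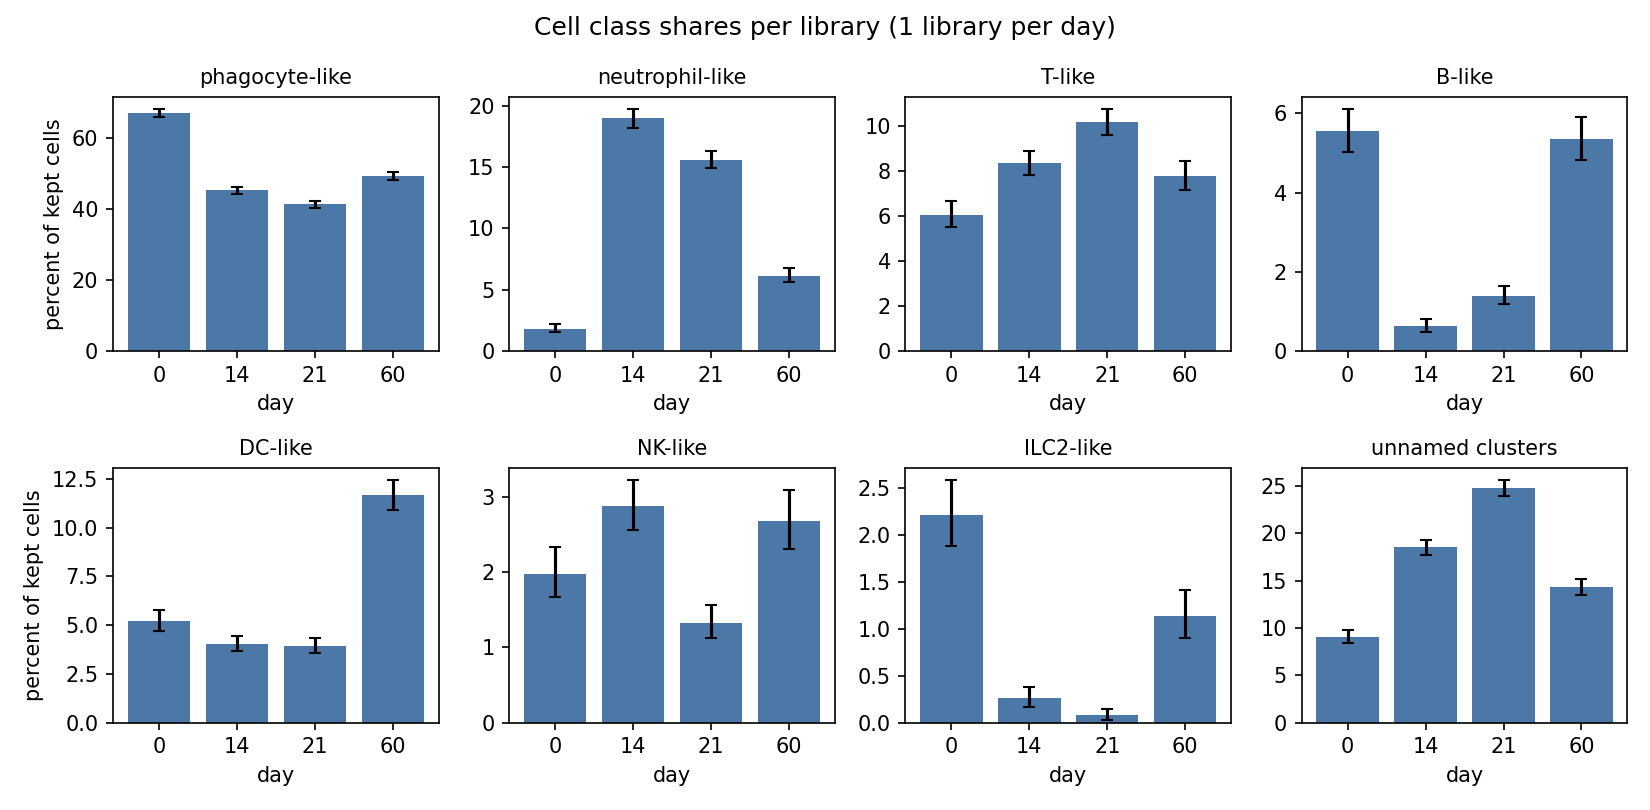
Share of each cell class among the kept cells of each library (1 library per day). Bars are exact 95% binomial intervals and cover counting error only.

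Within the phagocyte-like cells, macrophage-like cells were 95.3% on day 0, 40.3% on day 14, 71.5% on day 21 and 74.2% on day 60, and monocyte-like cells were 3.23%, 57.8%, 23.1% and 23.6%. With the 4 unnamed macrophage clusters counted as macrophage-like the order on day 14 turns: macrophage-like cells were then 95.6%, 56.0%, 80% and 77.4%, and monocyte-like cells 3.04%, 42.7%, 16.2% and 20.7%. Cluster 1, with a score of 0.628 for monocyte and 0.58 for macrophage, held 1795 of the 2616 monocyte-like cells on day 14, so the day 14 values rest on its name. Cluster 4, 1 of the 4 unnamed clusters, scored 0.644 for macrophage and 0.634 for monocyte and held 1049 cells on day 14. The turned order rests on counting it as macrophage-like. Clusters 3, 0 and 6 held 29.8%, 19.9% and 17.2% of the phagocyte-like cells on day 0. Cluster 1, led by Nos2, Cxcl9, Inhba, Ass1 and Arg1, held 39.7% of them on day 14, cluster 5, led by Ccl8 and Fabp5, held 31.5% on day 21, and clusters 0 and 8 held 22.5% and 19.2% on day 60. On day 0, cluster 10, led by Hspa1a, Hspa1b and Jun, held 11.5%, and cluster 14, led by Lyve1, Jun, Hspb1 and Fcna, held 15.1%. The comparisons below sum over all phagocyte-like cells, so they mix a different make-up of cells with different levels within a cell type.

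Interferon-gamma response genes were higher in phagocyte-like cells of the day 14 library than on day 0 (list median 2.95, 27 of 29 measured members higher). Cxcl9, a chemokine that attracts activated T cells, was 61.0-fold (55.7 to 67.0) higher, Gbp4 57.1-fold (46.5 to 70.8) and Nos2 1869-fold (639 to 9063; 3 UMIs on day 0). Ly6i was 828-fold (547 to 1322) higher, Saa3 609.9-fold (513 to 732), Arg1 507-fold (400.3 to 651) and Ass1 157-fold (139.9 to 176). HIF-1 targets and glycolysis genes had a median of 2.23 (23 of 30 higher), with Vegfa 17.4-fold (15.9 to 19.0), Egln3 30.4-fold (22.7 to 41.6), Pgk1 10.8-fold (10.4 to 11.2) and Hif1a 6.33-fold (6.07 to 6.60) higher. Nos2, Cxcl9, Arg1 and Ass1 are among the genes that lead cluster 1, and the median of all genes was -0.12.

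Genes of antigen presentation and respiration were also higher on day 14. The MHC class I list had a median of 0.92 (Tap1 7.92-fold (7.45 to 8.43), Nlrc5 5.93-fold (4.93 to 7.19)), the MHC class II list 0.68 (percentile 98.7; Ciita 2.29-fold (1.99 to 2.63), H2-DMa 2.85-fold (2.80 to 2.91)) and oxidative phosphorylation 0.93 (Cox5a 3.43-fold (3.35 to 3.51)). Genes of resident cardiac macrophages were lower, with a median of -2.95 and 20 of 20 members lower. Lyve1 was lower by 21.4-fold (19.9 to 22.9), Vsig4 by 25.1-fold (23.2 to 27.1), Cd163 by 14.3-fold (13.6 to 15.0), Cd207 by 30.8-fold (28.9 to 32.9) and Cd209g by 125-fold (62.9 to 290.2), while Ccr2, the receptor that marks recruited monocytes, was 6.63-fold (6.32 to 6.95) higher. AA467197 (346-fold, 261 to 469), Inhba (191-fold, 158 to 234) and Ly6a (198-fold, 156 to 256) were also higher on day 14. Fcna (17.1-fold, 15.9 to 18.5) was also lower on day 14. Il1b, Cd74 and Trem2 had ratios of 1.13 (1.12 to 1.13), 1.14 (1.14 to 1.14) and 0.552 (0.540 to 0.565) on day 14.

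Other lists on day 14 held members on both sides. Inflammatory cytokines and chemokines had a median of -0.21 (percentile 6.08): Ccl8 was 7.52-fold (7.33 to 7.70) higher, whereas Ccl4 was lower by 12-fold (11.8 to 12.1), Cxcl1 by 11.4-fold (11.3 to 11.5) and Ccl3 by 10.5-fold (10.3 to 10.6). Type I interferon genes stood at -0.47, with Ifit1 lower by 11.2-fold (10.5 to 12) and Ifnb1 by 81.0-fold (65.5 to 101). With the 4 macrophage clusters left unnamed counted in, that list stood at -0.80 (13 of 23 lower). Complement C1q and scavenger receptor genes stood at -1.65, with Cd36 lower by 8.67-fold (8.20 to 9.17), but C3 was 27.4-fold (25.6 to 29.4) and Cfb 73.0-fold (64.7 to 82.7) higher. Lysosomal and lipid-associated genes stood at 0.06 (percentile 38.5), profibrotic and matrix factors at -0.04 (percentile 21.0), cell cycle genes at 0.08 (percentile 96.5) and sex-linked transcripts at -0.07 (percentile 46.5). Among profibrotic factors, Spp1 was 3.43-fold (3.31 to 3.56) and Timp1 9.41-fold (8.69 to 10.2) higher. Glucocorticoid response genes stood at -1.73 and, like the lower chemokines, stood beside a stress and dissociation list at -1.31 (Jun lower by 7.59-fold (7.47 to 7.71)). With the 4 macrophage clusters left unnamed counted in, Gpnmb, 1.24-fold higher on day 14 and 1.93-fold on day 21, stood at ratios of 0.502 and 0.854, Inhba was 126-fold higher on day 14, and on that day the lysosomal list stood at -0.38 (percentile 1.37) and the cell cycle list at -0.16 (percentile 70.3).

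Interferon-gamma, HIF-1 and antigen presentation genes were also higher in phagocyte-like cells of the day 21 library than on day 0. Interferon-gamma genes had a median of 2.03 (23 of 28 higher; Cxcl9 17.9-fold (16.3 to 19.7), Nos2 290.3-fold (99.1 to 1409.8; 3 UMIs on day 0)), HIF-1 targets and glycolysis 1.36 (Vegfa 14.7-fold (13.4 to 16.1)), MHC class II 0.95 (H2-Eb1 2.13-fold (2.11 to 2.14)), MHC class I 0.74 (B2m 2.23-fold (2.21 to 2.26)) and oxidative phosphorylation 0.58. Resident macrophage genes stood at -2.97 (20 of 20 lower), with Lyve1 lower by 24.8-fold (22.8 to 26.9) and Cd163 by 17.4-fold (16.4 to 18.4). Fn1, a matrix protein, was 12.9-fold (12.3 to 13.5) and Spp1 7.62-fold (7.36 to 7.88) higher, with the profibrotic list at 0.32 (percentile 96.1). Complement genes stood at -0.92, lysosomal genes at 0.25 (percentile 85.3), type I interferon at -0.15 (percentile 11.1; Irf7 2.45-fold (2.38 to 2.52) higher) and the inflammatory list at -0.26 (percentile 2.67), beside a stress list at -1.58. With the 4 unnamed macrophage clusters counted in, the lysosomal list stood at -0.08 (percentile 18.5) and type I interferon at -0.41 (percentile 0.310) on day 21. The inflammatory list then stood at -0.44 (percentile 0.540). Saa3 (332-fold, 279.2 to 399) and Arg1 (309.9-fold, 245 to 398) were also higher on day 21. Ly6i (320.2-fold, 211 to 511), Ly6a (119-fold, 94.0 to 154) and AA467197 (104-fold, 78.2 to 141) were higher on day 21. Inhba (74.7-fold, 61.6 to 91.5) and AW112010 (47.9-fold, 44.6 to 51.4) were higher on day 21. Ass1 (43.9-fold, 39.2 to 49.4), Hif1a (3.47-fold, 3.33 to 3.63) and Ccr2 (6.29-fold, 6.00 to 6.60) were higher on day 21. Vsig4 (17.5-fold, 16.3 to 18.8) and Hpgd (16.7-fold, 15.7 to 17.7) were also lower on day 21. Cd207 (13.5-fold, 12.9 to 14.1) and Sult1a1 (12.7-fold, 11.7 to 13.8) were lower on day 21. Il1b, Cd74 and Trem2 had ratios of 0.736 (0.730 to 0.742), 1.45 (1.45 to 1.46) and 0.980 (0.960 to 0.999) on day 21.

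In phagocyte-like cells of the day 60 library against day 0, Fn1 was 18.5-fold (17.6 to 19.4), Vcan 23.6-fold (20.5 to 27.4), Spp1 11.4-fold (11 to 11.8), Thbs1 5.66-fold (5.37 to 5.96) and Ccr2 5.55-fold (5.28 to 5.83) higher, and the profibrotic list stood at 0.25 (percentile 97.8). Saa3 was 492-fold (414 to 591) and Arg1 168-fold (133 to 216) higher, and the HIF-1 list stood at 0.57, MHC class II at 0.49, oxidative phosphorylation at 0.38 and cell cycle genes at 0.57 (18 of 37 higher; Ube2c 3.38-fold (3.06 to 3.75)). The interferon-gamma list stood at 0.12 (percentile 84.7), with Cxcl9 at 9.53 against 10.7 CPM, and MHC class I at -0.02 (percentile 26.7). Resident macrophage genes stood at -0.72 (Lyve1 lower by 2.47-fold (2.39 to 2.56)). Type I interferon genes (-1.10, 18 of 23 lower), inflammatory genes (-0.52; Tnf lower by 2.94-fold (2.89 to 2.98)), complement genes (-0.37) and lysosomal genes (-0.30) were lower, beside a stress list at -1.0. With the 4 unnamed macrophage clusters counted in, Spp1 on day 60 was 6.83-fold higher. Slpi (32.6-fold, 29.8 to 35.6) and Plac8 (6.34-fold, 6.04 to 6.67) were also higher on day 60. Chil3 (6.14-fold, 5.75 to 6.56) and Hif1a (2.01-fold, 1.92 to 2.11) were higher on day 60. Ifnb1 (7.75-fold, 7.09 to 8.49) and Ifit1 (4.01-fold, 3.80 to 4.24) were also lower on day 60. Jun (3.58-fold, 3.52 to 3.63), Hspa1a (3.55-fold, 3.49 to 3.61) and Ifih1 (2.99-fold, 2.87 to 3.13) were lower on day 60. Il1b and Cd74 had ratios of 0.979 (0.972 to 0.987) and 1.17 (1.17 to 1.18) on day 60. Trem2, Cxcl9 and Nos2 had ratios of 0.788 (0.770 to 0.807), 0.891 (0.777 to 1.02) and 2.79 (0.670 to 16.3; 3 UMIs on day 0) on day 60.

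**Figure D2:**
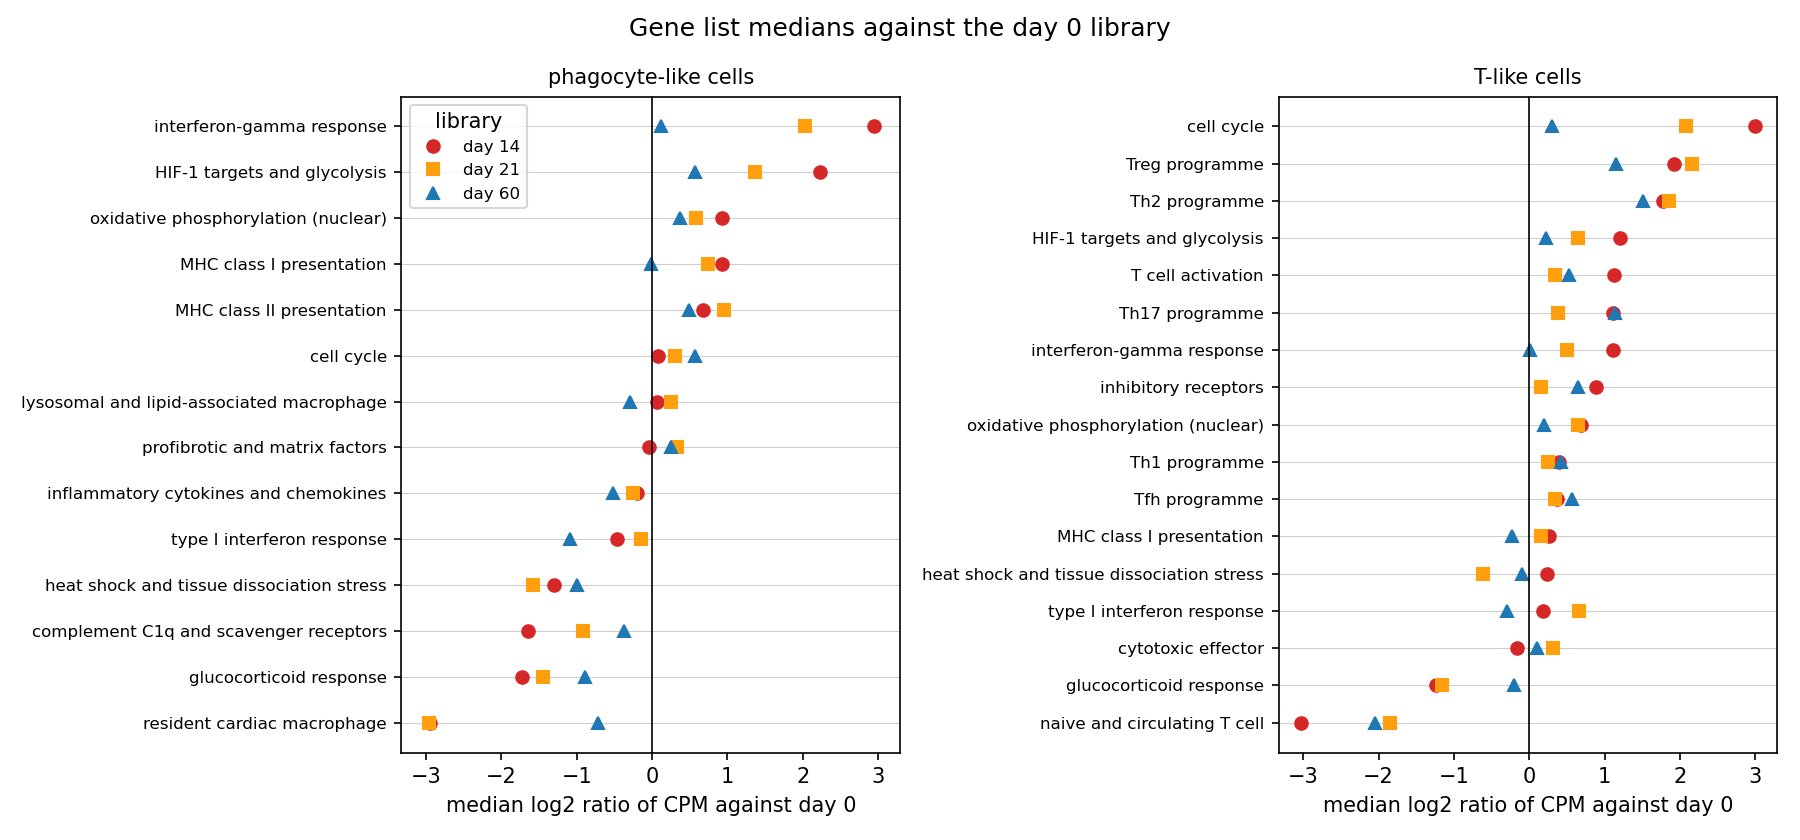
Median log2 ratio of each gene list against the day 0 library in phagocyte-like and T-like cells. The stress and dissociation list is shown beside the others, and each point compares 1 library with 1 library.

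Between the later libraries, interferon-gamma genes of phagocyte-like cells were lower on day 21 than on day 14 (median -1.08, 29 of 29 lower), with Nos2 lower by 6.44-fold (6.05 to 6.85) and Cxcl9 by 3.41-fold (3.34 to 3.48). HIF-1 targets stood at -0.76, while lysosomal and lipid-associated genes (0.63; Trem2 1.77-fold (1.74 to 1.81)), profibrotic factors (0.50; Spp1 2.22-fold (2.18 to 2.26)) and type I interferon genes (0.50; Irf7 2.44-fold (2.38 to 2.51)) were higher; the stress list was at -0.06 (percentile 38.4). Ms4a7 (3.08-fold, 3.01 to 3.16) and Cd72 (2.94-fold, 2.81 to 3.08) were also higher on day 21 than on day 14. Oasl1 (2.52-fold, 2.41 to 2.63) and Emp1 (2.36-fold, 2.29 to 2.43) were higher on day 21 than on day 14. Ass1 (3.57-fold, 3.51 to 3.63) and Gbp2 (3.56-fold, 3.47 to 3.65) were also lower on day 21 than on day 14. Hif1a and Il1b had ratios of 0.549 (0.537 to 0.561) and 0.654 (0.649 to 0.659) on day 21 against day 14. Cd74, Lyve1 and Ccr2 had ratios of 1.27 (1.27 to 1.28), 0.863 (0.777 to 0.958) and 0.949 (0.929 to 0.969) on day 21 against day 14. On day 60 against day 21, resident macrophage genes were higher (1.92, 20 of 20; Vsig4 11.5-fold (10.7 to 12.4), Lyve1 10.0-fold (9.21 to 10.9)), as was Retnla (11.9-fold (11.3 to 12.5)), which is induced by type 2 cytokines. Interferon-gamma (-1.72; Cxcl9 lower by 20.1-fold (18.2 to 22.2)), type I interferon (-1.03), MHC class I (-0.81) and HIF-1 genes (-0.69) were lower. Complement (0.68) and inflammatory genes (0.38) were higher on day 60 than on day 21, beside a stress list at 0.62. Cd207 (9.99-fold, 9.51 to 10.5) and Cxcl13 (8.80-fold, 8.47 to 9.15) were also higher on day 60 than on day 21. Ly6i (149-fold, 112 to 205) and Ly6a (67.6-fold, 56.2 to 82.1) were also lower on day 60 than on day 21. AA467197 (59.4-fold, 47.7 to 75.1), Inhba (22.4-fold, 20.1 to 25.1) and Nos2 (104-fold, 52.6 to 241) were lower on day 60 than on day 21. Hif1a, Il1b and Cd74 had ratios of 0.579 (0.559 to 0.599), 1.33 (1.32 to 1.34) and 0.806 (0.804 to 0.808) on day 60 against day 21. Spp1, Trem2 and Ccr2 had ratios of 1.5 (1.47 to 1.52), 0.805 (0.787 to 0.823) and 0.883 (0.861 to 0.905) on day 60 against day 21.

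T-like cells of the day 14 library held more transcripts of effector cytokines than those of day 0. Csf2, which encodes the growth factor GM-CSF, was 167-fold (109 to 269.9) higher, Il17a 12.9-fold (11.3 to 14.8), Il17f 3.35-fold (2.73 to 4.14), Il22 36-fold (14.0 to 133) and Ifng 6.70-fold (5.52 to 8.21). CD4 T-like cells held 68.0% of the Il17a UMIs on day 14 and 77.4% on day 21, whereas gamma-delta T-like cells held all 219 on day 0 and 812 of 890 (91.2%) on day 60. For Ifng, CD8 T-like cells held 86.9% of the UMIs on day 0 and CD4 T-like cells 83.9% on day 14. Within CD8 T-like cells Ifng stood at 160 CPM on day 0 and 70.2 on day 14 (93 and 26 UMIs). Il17a, Csf2 and Ifng lead cluster 26, 1 of the 2 CD4 clusters, and Il17a is among the leading genes of cluster 29, the gamma-delta cluster. Thinned to 1000 UMIs per cell, Il17a was found in 2.86% (1.48 to 4.94), 21.1% (18.3 to 24), 6.98% (5.53 to 8.68) and 9.14% (6.84 to 11.9) of T-like cells on days 0, 14, 21 and 60 (not thinned 3.81%, 33.7%, 11.4% and 17.0%), against 0 of 4640 (limit 0.0647%), 0.0221%, 0.0459% and 0.0887% of phagocyte-like cells; median depths were 4590.5, 7283.5, 5866.5 and 4798 UMIs in T-like and 8341, 14075.5, 11753 and 10477 in phagocyte-like cells.

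**Figure D3:**
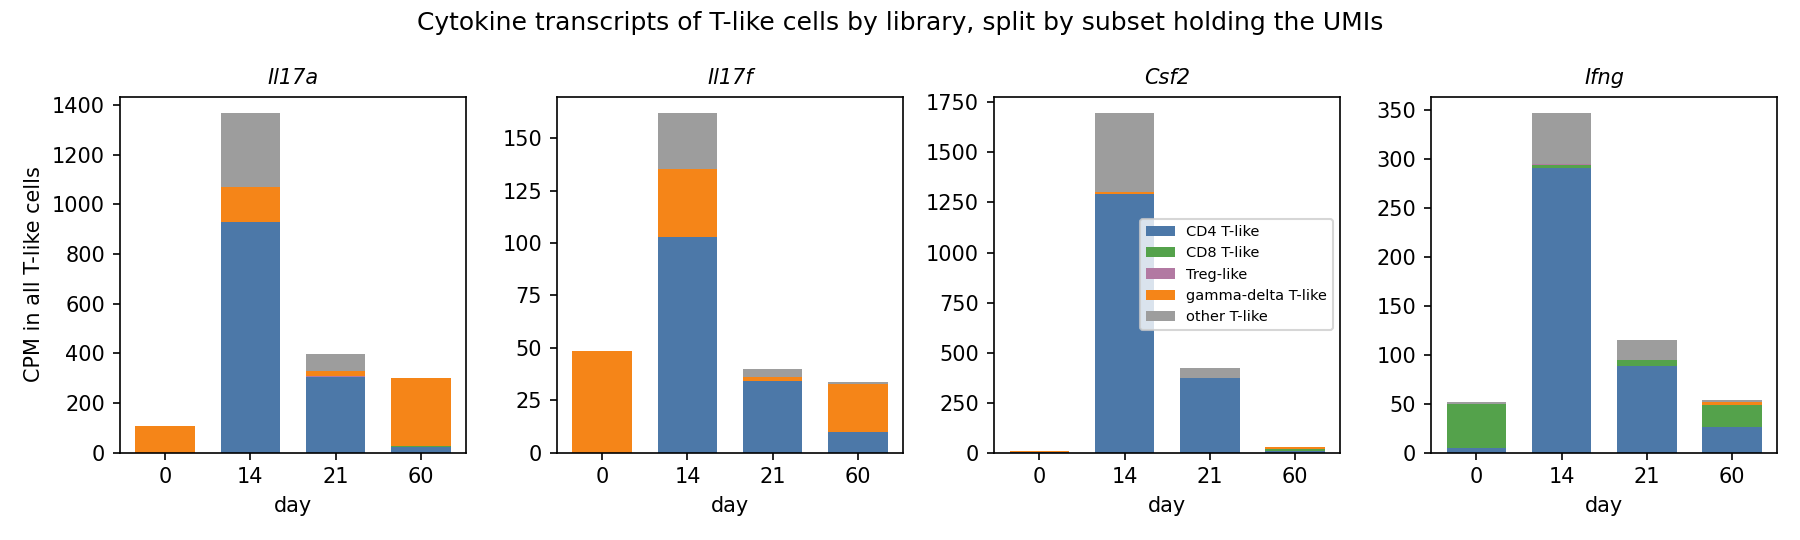
CPM of Il17a, Il17f, Csf2 and Ifng in all T-like cells of each library, split by the subset that held the UMIs. Il17a, Csf2 and Ifng helped define cluster 26, and Il17a cluster 29, so the split follows in part from the clustering.

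Csf2 was found in 0.476% of thinned T-like cells on day 0 and in 17.3%, 7.73% and 1.68% on days 14, 21 and 60 (not thinned 1.90%, 28.5%, 13% and 5.6%), against 0.841%, 0.0663%, 0.0688% and 0.0591% of phagocyte-like cells. On day 0 the Csf2 share rested on 2 of 420 T-like cells (0.0577 to 1.71), and 1.85% of phagocyte-like cells held a UMI when not thinned. Ifng was found in 3.57%, 8.25%, 4.19% and 2.24% of T-like cells (not thinned 8.57%, 18.3%, 9.12% and 9.33%), against 0 (limit 0.0647%), 0.0221%, 0 (limit 0.0688%) and 0 (limit 0.0887%) of phagocyte-like cells. Foxp3 was found in 0.952%, 4.90%, 10.1% and 2.05% of T-like cells (not thinned 2.14%, 13.6%, 28.5% and 5.6%), against 0.0431%, 0.0221%, 0.0918% and 0.0887% of phagocyte-like cells.

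The make-up of the T-like cells also differed between libraries. CD4 T-like cells were 9.76% (7.10 to 13) of T-like cells on day 0, 53.5% (50.0 to 56.9) on day 14, 28.3% (25.6 to 31.1) on day 21 and 15.9% (12.9 to 19.2) on day 60, and CD8 T-like cells were 26.7%, 7.42%, 23.6% and 22.4%. Treg-like cells, which restrain other T cells, were 1.90% (0.826 to 3.72), 9.33% (7.44 to 11.5), 25.1% (22.6 to 27.8) and 5.78%, and gamma-delta T-like cells 12.6% (9.60 to 16.2), 7.66%, 2.70% (1.82 to 3.86) and 45.5% (41.2 to 49.8). T-like cells outside the named subsets were 49.0%, 22.1%, 20.3% and 10.4% on days 0, 14, 21 and 60. Clusters 30 and 19 held 47.9% and 26.7% of the T-like cells on day 0, clusters 20, 26 and 36 held 31.2%, 22.2% and 18.7% on day 14, clusters 28 and 19 held 25.1% and 23.6% on day 21, and cluster 29 held 45.5% on day 60. Cluster 30 stayed outside the named subsets, with scores of 0.676 for CD4 T and 0.734 for CD8 T. The low CD4 T-like share of day 0 therefore depends on the naming rule and is not a share of all CD4 cells. The Treg-like and gamma-delta T-like sets are each 1 cluster, so their shares and the levels of their leading genes in all T-like cells are not separate observations. The day 21 library alone held cluster 40, which carried thymocyte genes. Whether cells of its source add to the CD8 T-like share of day 21 was not tested.

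Cell cycle genes were higher in T-like cells of the day 14 library than on day 0 (median 2.99, 35 of 37 higher; Mki67 11.1-fold (7.54 to 17.1)), and the Treg (1.93; Tnfrsf9 22.9-fold (18.1 to 29.5), Foxp3 4.09-fold (2.84 to 6.08)), Th17 (1.11) and Th2 lists (1.78; Il13 at least 69.0-fold) were higher too. T cell activation genes stood at 1.12, inhibitory receptors at 0.88 (Lag3 26.3-fold (12.7 to 65.7), Pdcd1 ratio 0.817), HIF-1 targets at 1.21 (Tpi1 12.2-fold (9.94 to 15.2)), oxidative phosphorylation at 0.68 and interferon-gamma genes at 1.11 (Iigp1 11.3-fold (5.68 to 26.4)). The Treg list shares Il10 and Il1rl1 with the Th2 list, and Ctla4, Tigit and Entpd1 with the inhibitory receptors. It shares Il2ra, Tnfrsf4, Tnfrsf9, Tnfrsf18 and Icos with the activation list. The medians of these lists, here and on later days, are therefore not separate observations. Genes of naive and circulating T cells were lower, with a median of -3.03 (13 of 13 lower; Klf2 by 11.7-fold (10.9 to 12.6), Igfbp4 by 14.4-fold (12.1 to 17.3)). The Th1 list stood at 0.40 (percentile 91.5), Tfh at 0.37 (percentile 79.9), cytotoxic effectors at -0.16 (percentile 17.2; Ccl5 lower by 3.91-fold (3.74 to 4.09), Gzmb 4.95-fold (4.32 to 5.69) higher), type I interferon at 0.18 (percentile 88.5) and MHC class I at 0.27 (percentile 67.4). Cluster 36, with Rrm2, Top2a and Ube2c among its leading genes, was 1.19%, 18.7%, 11.3% and 1.68% of T-like cells on days 0, 14, 21 and 60. T-like cells outside the named subsets held 90.7% and 90.3% of the Mki67 UMIs on days 14 and 21, so the cell cycle values were not separated from the share of such cells. Glucocorticoid response genes stood at -1.24, beside a stress list at 0.23 (percentile 59.1). Il1r2 (846-fold, 152 to 33420.5; 1 UMI on day 0) and Spp1 (579.7-fold, 104 to 22908; 1 UMI on day 0) were also higher on day 14. Ermn (at least 85.7-fold), Nrgn (197-fold, 67.3 to 956; 3 UMIs on day 0) and Igfbp7 (139.6-fold, 59.7 to 430.2) were higher on day 14. Ccl1 (72.4-fold, 44.5 to 127), Dusp14 (51.4-fold, 24.9 to 128) and Il10 (21.9-fold, 3.84 to 877; 1 UMI on day 0) were higher on day 14. Pik3ip1 (18.3-fold, 13.5 to 25.3) and Fam101b (14.3-fold, 12.1 to 16.8) were also lower on day 14. Tubb2a (11.4-fold, 9.39 to 13.8) and Txnip (10.0-fold, 8.55 to 11.8) were lower on day 14. Tbx21 and Pdcd1 had ratios of 1.15 (0.888 to 1.5) and 0.817 (0.739 to 0.906) on day 14. Spp1 and Retnla are also transcripts of phagocyte-like cells, and their UMIs in other classes were screened for free RNA only by the rule for named genes.

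In T-like cells of day 21, Treg genes were higher than on day 0, with a list median of 2.16 (15 of 16 higher), with Foxp3 8.88-fold (6.22 to 13.1), Ikzf4 8.28-fold (4.57 to 16.7) and Ctla4 5.06-fold (4.53 to 5.66) higher. Cell cycle genes stood at 2.09, Th2 genes at 1.85 (Ccr8 11.9-fold (8.22 to 18)), HIF-1 targets at 0.65, type I interferon at 0.66 (Isg20 4.70-fold (3.19 to 7.20)) and naive genes at -1.85 (Klf2 lower by 6.38-fold (6.01 to 6.78)). The Th2 median was not separated from the larger share of Treg-like cells. Csf2 was 41.4-fold (27.1 to 67.0), Il17a 3.73-fold (3.26 to 4.30) and Ifng 2.22-fold (1.81 to 2.73) higher, with the Th17 list at 0.38 (percentile 94.0) and the Th1 list at 0.25 (percentile 91.0). CD4 T-like cells held 88.6%, 77.4% and 77.2% of these UMIs on day 21, and 74 of the 304 CD4 T-like cells belonged to 1 clonotype. The cytokine ratios were not computed without that clonotype. Within CD8 T-like cells Ifng was not higher, at 33.8 CPM (25.2 to 44.5) against 160 (129 to 196) on day 0. Glucocorticoid genes (-1.16) were lower, beside a stress list at -0.61. Counting cluster 40, left unnamed for its thymocyte genes, as T-like gave medians of 1.87 for Treg, 0.16 for Th17, -0.042 for Th1 and 2.80 for the cell cycle. That setting does not show whether other T-like cells of day 21 share the source of that cluster. Il1r2 (663-fold, 119 to 26193; 1 UMI on day 0), Spp1 (306-fold, 54.8 to 12099; 1 UMI on day 0) and Nrgn (136-fold, 46.6 to 662; 3 UMIs on day 0) were also higher on day 21. Igfbp7 (76.5-fold, 32.7 to 236), Penk (64.2-fold, 31.1 to 160.0) and Ccl1 (41.2-fold, 25.3 to 72.2) were higher on day 21. Dusp14 (41.8-fold, 20.2 to 104), Il10 (27.1-fold, 4.77 to 1081; 1 UMI on day 0) and Mki67 (8.36-fold, 5.66 to 12.9) were higher on day 21. Cd163l1 (18.7-fold, 14.8 to 23.8) and Tubb2a (9.61-fold, 8.04 to 11.5) were also lower on day 21. Fam101b (8.04-fold, 7.05 to 9.18), Pik3ip1 (6.32-fold, 5.13 to 7.81) and S1pr1 (5.67-fold, 5.05 to 6.38) were lower on day 21. Il17f, Tbx21 and Pdcd1 had ratios of 0.824 (0.657 to 1.04), 0.812 (0.621 to 1.07) and 0.932 (0.844 to 1.03) on day 21. The 100 Il17f UMIs of day 0 came from 4 T-like cells. Not thinned, an Il17f UMI was found in 3.35% of T-like cells on day 21 against 0.952% on day 0.

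On day 60, Th17 genes were again higher than on day 0 (1.14, 12 of 13 higher; Il17a 2.84-fold (2.45 to 3.31)), in a library where gamma-delta T-like cells were the largest T subset. Within gamma-delta T-like cells, Il17a was not higher, at 633 CPM (590 to 678) on day 60 and 677 (590 to 773) on day 0. Il17f stood at 53.0 CPM (41.2 to 67.2) against 309 (252 to 376), but its 100 UMIs on day 0 came from 4 of 53 cells. These intervals treat UMIs of the same cell as independent. The share of these cells with an Il17f UMI, not thinned, was 6.15% (3.48 to 9.94) on day 60 and 7.55% (2.09 to 18.2) on day 0. The Il17a ratio over all T-like cells thus goes with the larger share of this subset. Areg, an epidermal growth factor family member, was 6.56-fold (5.29 to 8.21) higher, and the Treg (1.15; Foxp3 2.30-fold (1.53 to 3.56)) and Th2 lists (1.51) were higher. Inhibitory receptors stood at 0.64 (Pdcd1 1.47-fold (1.32 to 1.64)), activation genes at 0.53, Tfh genes at 0.57, Th1 genes at 0.43 and cell cycle genes at 0.30. Gamma-delta T-like cells held 74.9% of the Pdcd1 UMIs on day 60. Within them Pdcd1 was lower, at 610 CPM (568 to 655) against 1144 (1031 to 1267) on day 0. It was also lower in CD4 T-like cells (72.9 against 211) and higher in CD8 T-like cells (125 against 99.9) and those outside the named subsets (144 against 8.51). Naive genes were lower (-2.05; Ccr7 by 6.97-fold (6.32 to 7.70), Lef1 by 5.48-fold (4.73 to 6.37)), beside a stress list at -0.10 (percentile 17.7). Tnfrsf9 (5.38-fold, 4.18 to 7.02), Ern1 (4.86-fold, 3.80 to 6.30) and Furin (4.53-fold, 3.55 to 5.85) were also higher on day 60. Cd44 (3.20-fold, 2.70 to 3.82), Atf3 (3.21-fold, 2.61 to 3.98) and Il2ra (3.07-fold, 2.61 to 3.63) were higher on day 60. S100a6 (2.73-fold, 2.60 to 2.87), Csf2 (2.80-fold, 1.72 to 4.75) and Il10 (18.9-fold, 3.11 to 773; 1 UMI on day 0) were higher on day 60. Within CD4 T-like cells Csf2 stood at 53.0 against 61.1 CPM, but its 11 UMIs there on day 0 came from 1 of 41 cells. Not thinned, a Csf2 UMI was found in 7.06% (2.63 to 14.7) of CD4 T-like cells on day 60 against 2.44% (0.0617 to 12.9) on day 0. Within gamma-delta T-like cells Csf2 was not higher (21.0 against 27.8 CPM), with a UMI in 6.97% of cells, not thinned, against 11.3%. CD8 T-like cells held 31 of its 84 UMIs on day 60, in 6 of 120 cells, and 0 on day 0. Tubb2a (6.62-fold, 5.27 to 8.40), Actn1 (5.6-fold, 4.17 to 7.63) and Fam101b (4.49-fold, 3.85 to 5.25) were also lower on day 60. Il17f and Ifng had ratios of 0.699 (0.524 to 0.931) and 1.04 (0.808 to 1.34) on day 60. The 100 Il17f UMIs of day 0 came from 4 of 420 T-like cells. Not thinned, an Il17f UMI was found in 4.85% (3.19 to 7.03) of T-like cells on day 60 against 0.952% (0.260 to 2.42) on day 0. The UMI ratio and the share of cells thus point in opposite directions. Tbx21 and Mki67 had ratios of 0.699 (0.497 to 0.983) and 1.51 (0.930 to 2.5) on day 60.

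Between the later libraries, T-like cells of day 21 held lower Csf2 (by 4.03-fold (3.88 to 4.18)), Il17a (3.46-fold (3.32 to 3.6)) and Ifng (3.02-fold (2.81 to 3.26)) than those of day 14, and higher Foxp3 (2.17-fold (1.95 to 2.42)) and Ikzf2 (2.57-fold (2.40 to 2.75)). List medians were -0.89 for Th17, -0.59 for HIF-1 targets, -0.58 for the cell cycle and 0.88 for naive genes. The stress list stood at -0.49 (Hspa1a lower by 6.72-fold (6.20 to 7.30)). Cluster 40, left unnamed for its thymocyte genes, was found in the day 21 library alone. Whether cells of the same source lie among the T-like cells of day 21 was not tested. The naive gene median and the Cd27 and Cd8b1 ratios below were therefore not separated from such cells. Penk (3.52-fold, 3.18 to 3.89) and Cd27 (3.45-fold, 3.13 to 3.81) were also higher on day 21 than on day 14. Izumo1r (2.90-fold, 2.64 to 3.18) and Cd8b1 (2.60-fold, 2.32 to 2.92) were higher on day 21 than on day 14. Hspa1b (7.96-fold, 6.91 to 9.21), Lta (4.55-fold, 4.16 to 4.98) and Il17f (4.06-fold, 3.6 to 4.60) were also lower on day 21 than on day 14. Tbx21 and Il10 had ratios of 0.707 (0.595 to 0.838) and 1.24 (0.924 to 1.66) on day 21 against day 14. Pdcd1 and Mki67 had ratios of 1.14 (1.07 to 1.22) and 0.752 (0.688 to 0.822) on day 21 against day 14. On day 60 against day 21, cell cycle (-1.99, 35 of 37 lower), Treg (-1.35; Foxp3 lower by 3.86-fold (3.15 to 4.78)), inhibitory receptor (-1.11) and type I interferon genes (-0.70) were lower, and Csf2 was lower by 14.8-fold (11.9 to 18.6). Il17a was lower by 1.32-fold (1.22 to 1.42), and the stress list stood at 0.65. Cd163l1 (15.0-fold, 11.9 to 19.1) and Lmo4 (13.6-fold, 11.8 to 15.6) were also higher on day 60 than on day 21. Blk (11.8-fold, 9.27 to 15.1), Pxdc1 (9.64-fold, 7.86 to 11.9) and Actn2 (5.50-fold, 4.77 to 6.36) were higher on day 60 than on day 21. Nrgn (24.4-fold, 16.3 to 38.2) and Ccl1 (18.1-fold, 13.8 to 24.4) were also lower on day 60 than on day 21. Penk (11.9-fold, 9.09 to 15.9), Ifng (2.13-fold, 1.80 to 2.54) and Mki67 (5.55-fold, 4.23 to 7.41) were lower on day 60 than on day 21. Il17f and Tbx21 had ratios of 0.848 (0.672 to 1.06) and 0.860 (0.651 to 1.12) on day 60 against day 21. Il10 and Pdcd1 had ratios of 0.696 (0.439 to 1.07) and 1.58 (1.46 to 1.70) on day 60 against day 21. Cd163l1 and Blk are markers used to name gamma-delta T-like cells.

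Neutrophil-like cells of the day 14 library held higher interferon-gamma response genes than those of day 0 (median 2.72, 27 of 28 higher), with Gbp2b 68.3-fold (26.6 to 251) and Cxcl9 at least 33.2-fold higher. Granule and maturation genes stood at 1.46, 1.85 and 0.93 on days 14, 21 and 60, and Ngp, a granule protein of immature neutrophils, was 12.7-fold (10.4 to 15.6), 25.5-fold (20.9 to 31.4) and 7.14-fold (5.84 to 8.82) higher. Ngp, Camp and Ltf lead cluster 23, which held 1.56%, 8.43%, 15.8% and 4.73% of neutrophil-like cells on days 0, 14, 21 and 60. HIF-1 targets stood at 1.5, 1.08 and 0.61, and type I interferon genes at 0.44, 0.52 and -0.54 (day 60 percentile 4.10). The interferon-gamma list stood at 1.60 on day 21 and -1.13 on day 60, where Thbs1 was lower by 107-fold (56.8 to 225), Cxcl10 by 9.47-fold (6.68 to 13.6) and Cd274 by 5.45-fold (4.15 to 7.14). Aged and activated neutrophil genes (-1.70) and inflammatory genes (-1.49) were lower on day 60, beside stress lists at -1.67, -1.41 and -1.01. The day 0 library held 128 such cells, 89.1% of them in cluster 7, against 73.2% in cluster 2 on day 14; the median of all genes was -0.42, -0.23 and -0.20. The TMM factors against day 0 were -0.66, -0.44 and -0.35 in log2 on days 14, 21 and 60, so that scaling would raise every log2 ratio and list median here by that size. AW112010 (at least 147-fold) and Saa3 (562-fold, 101 to 22214; 1 UMI on day 0) were also higher on day 14. Ly6i (379-fold, 67.9 to 14956; 1 UMI on day 0), Stfa2 (147-fold, 50.4 to 715; 3 UMIs on day 0) and Tgtp1 (at least 43.2-fold) were higher on day 14. Acot1 (58.7-fold, 41.7 to 83.4) and Ciart (21.4-fold, 16.1 to 28.3) were also lower on day 14. Dusp2 (16.2-fold, 14.4 to 18.1) and Nr4a1 (14.2-fold, 13.3 to 15.2) were lower on day 14. Ly6i (156-fold, 28.0 to 6167; 1 UMI on day 0) and Stfa2 (80.1-fold, 27.4 to 388; 3 UMIs on day 0) were also higher on day 21. Saa3 (147-fold, 26.3 to 5800.4; 1 UMI on day 0) and Mif (64.2-fold, 17.8 to 530.3; 2 UMIs on day 0) were higher on day 21. Acot1 (45.5-fold, 32.5 to 64.3) and Ciart (11-fold, 8.45 to 14.1) were also lower on day 21. Dusp2 (8.91-fold, 8.01 to 9.89) and Thbs1 (8.49-fold, 7.24 to 9.93) were lower on day 21. Stfa2 (65.6-fold, 22.4 to 319; 3 UMIs on day 0) and Wfdc17 (19.0-fold, 15.9 to 23) were also higher on day 60. Lrg1 (12.4-fold, 10.0 to 15.6), BC117090 (13.8-fold, 9.05 to 22) and Stfa3 (50.4-fold, 8.96 to 1999; 1 UMI on day 0) were higher on day 60. Bcl2a1d (16.9-fold, 13.7 to 21.1), Bcl2a1a (17.1-fold, 13.6 to 21.6) and Acot1 (18-fold, 11.7 to 28.4) were also lower on day 60.

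Between the later libraries, neutrophil-like cells of day 21 held lower interferon-gamma genes than those of day 14 (-1.24, 27 of 28 lower) and higher granule genes (0.63), against a median of all genes of 0.24. On day 60 against day 21, interferon-gamma (-2.60, 28 of 28 lower), type I interferon (-1.35) and granule genes (-1.07) were lower, with the stress list at 0.11 (percentile 68.6). Camp (2.44-fold, 2.39 to 2.49), Chil3 (2.22-fold, 2.05 to 2.41) and Nr4a1 (2.15-fold, 2.05 to 2.25) were also higher on day 21 than on day 14. F3 (5.82-fold, 5.22 to 6.51) and AW112010 (4.05-fold, 3.89 to 4.22) were also lower on day 21 than on day 14. Saa3 (3.83-fold, 3.70 to 3.97) and Gbp5 (3.59-fold, 3.35 to 3.86) were lower on day 21 than on day 14. Tsc22d3 (3.06-fold, 2.87 to 3.27) and Adam19 (2.69-fold, 2.33 to 3.09) were also higher on day 60 than on day 21. Adgre5 (2.37-fold, 2.21 to 2.55), Nlrp12 (2.42-fold, 2.06 to 2.84) and Prr5l (2.37-fold, 2.04 to 2.74) were higher on day 60 than on day 21. Ly6i (194-fold, 75.8 to 714) and Gbp4 (at least 87.0-fold) were also lower on day 60 than on day 21. Tgtp1 (136-fold, 37.6 to 1124; 2 UMIs on day 60) and Cxcl10 (22.8-fold, 17.3 to 30.6) were lower on day 60 than on day 21.

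B-like cells of every later library held lower naive follicular genes than on day 0, with medians of -1.30, -1.32 and -1.16. Fcer2a, which encodes the CD23 receptor of follicular B cells, was lower by 10.8-fold (7.07 to 17.3), 5.04-fold (4.07 to 6.29) and 4.85-fold (4.20 to 5.62). Marginal zone, B1 and memory genes stood at 1.74, 1.32 and 1.31 (Plac8 3.51-fold (3.13 to 3.93) higher on day 14), cell cycle genes at 2.26, 1.48 and 2.44 (Ube2c 44.2-fold (20.1 to 121) higher on day 60) and B cell activation genes at 0.33, 0.53 and -0.19 (day 60 percentile 50.6). MHC class II genes stood at -0.42, -0.41 and -0.53 (percentiles 2.06, 2.92 and 1.31). Day 14 held 64 B-like cells, the stress list stood at -0.37, -0.46 and -0.07 (percentiles 0.930, 0.240 and 58.6), and the median of all genes was -0.24, -0.25 and -0.24. Ube2c is among the leading genes of cluster 48, which held 0, 4, 6 and 23 B-like cells on days 0, 14, 21 and 60 with a median of 20194 UMIs, and the cell cycle values were not separated from these cells. Ube2c (38.5-fold, 16.9 to 108) and Fgl2 (28.4-fold, 14.2 to 64.2) were also higher on day 14. Cd300lf (16-fold, 8.33 to 33.9), Top2a (15.0-fold, 8.16 to 29.6) and S100a6 (6.79-fold, 6.19 to 7.45) were higher on day 14. Sesn1 (13.7-fold, 5.77 to 42.6), Zfp36l2 (5.50-fold, 4.13 to 7.47) and Ets1 (4.71-fold, 3.84 to 5.83) were also lower on day 14. Fgl2 (20.0-fold, 10.2 to 44.7) and Ly6a (17.9-fold, 9.71 to 36.8) were also higher on day 21. Cd300lf (17.1-fold, 9.26 to 35.2), S100a6 (4.39-fold, 4.02 to 4.80) and Ass1 (5.10-fold, 3.84 to 6.86) were higher on day 21. Treml2 (10.0-fold, 5.96 to 18.2) and Zfp318 (7.11-fold, 4.63 to 11.4) were also lower on day 21. Cnr2 (7.76-fold, 4.57 to 14.2) and Plk2 (7.12-fold, 4.49 to 11.9) were lower on day 21. Retnla (105-fold, 35.8 to 511; 3 UMIs on day 0) and Fgl2 (21.3-fold, 11.1 to 47.0) were also higher on day 60. Plscr1 (4.90-fold, 3.69 to 6.62) and Ass1 (4.68-fold, 3.6 to 6.18) were higher on day 60. Treml2 (5.32-fold, 4.05 to 7.05), Ccr7 (3.85-fold, 3.59 to 4.12) and Neurl3 (4.13-fold, 3.34 to 5.14) were also lower on day 60. Ly6a (4.06-fold, 2.41 to 7.30) was also higher on day 21 than on day 14. Ube2c (5.45-fold, 3.51 to 8.68) was also lower on day 21 than on day 14. Retnla (216-fold, 38.6 to 8541; 1 UMI on day 21) and Ube2c (6.26-fold, 4.30 to 9.45) were also higher on day 60 than on day 21. Hspa1a (3.29-fold, 2.57 to 4.27) and Dnajb1 (2.76-fold, 2.26 to 3.41) were higher on day 60 than on day 21. Ly6a (12.5-fold, 8.24 to 19.7), Rgs1 (4.21-fold, 3.40 to 5.22) and Bcl2a1b (2.65-fold, 2.16 to 3.25) were also lower on day 60 than on day 21.

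NK-like cells of the day 14 and 21 libraries held higher cell cycle genes than on day 0 (1.92 and 0.87; Mki67 7.63-fold (4.78 to 13) on day 14), and those of day 60 lower (-0.78). Cytotoxic effector genes stood at 0.48, 0.29 and -0.13 (percentiles 99.7, 97.1 and 4.60), and Klrg1, a receptor of mature NK cells, was 3.13-fold (2.19 to 4.62) and 3.40-fold (2.32 to 5.12) higher on days 14 and 21. Cluster 32 held 82.5% of the NK-like cells on day 0 and 84.8% on day 60, and cluster 33, led by Gzma, Gzmb and Prf1, held 67.0% on day 14 and 63.6% on day 21. Cluster 43, with Hist1h2ap among its leading genes, held 2.92%, 20.8%, 5.71% and 0.543% on days 0, 14, 21 and 60, and the cell cycle values were not separated from its share. The stress list stood at -0.92, -1.22 and -0.37. Plac8 (61.7-fold, 29.9 to 154) and Spp1 (11.5-fold, 7.10 to 19.8) were also higher on day 14. Birc5 (9.68-fold, 5.71 to 17.8) and Rrm2 (7.13-fold, 4.11 to 13.5) were higher on day 14. Adamts9 (15.2-fold, 9.91 to 24.1) and Rab4a (9.99-fold, 6.89 to 14.7) were also lower on day 14. Tmem176b (6.63-fold, 5.54 to 7.96) and Inpp4b (6.59-fold, 5.28 to 8.26) were lower on day 14. Plac8 (46.4-fold, 22.3 to 116) and Spp1 (9.67-fold, 5.90 to 16.9) were also higher on day 21. Gzma (5.30-fold, 4.94 to 5.68), Myb (8.00-fold, 4.19 to 17.1) and Serpinb9b (4.59-fold, 3.51 to 6.08) were higher on day 21. Adamts9 (18.7-fold, 9.19 to 44.5) and Inpp4b (7.70-fold, 5.48 to 11.1) were also lower on day 21. Socs2 (8.13-fold, 5.30 to 13) and Rab4a (8.10-fold, 4.89 to 14.2) were lower on day 21. Ccdc184 (6.24-fold, 3.70 to 11.2) and Furin (5.34-fold, 3.15 to 9.66) were also higher on day 60. Gzmb (2.96-fold, 2.61 to 3.36) was also lower on day 60. Ccl4 (2.73-fold, 2.55 to 2.92) was also higher on day 21 than on day 14. Areg (7.30-fold, 4.55 to 12.5) and Gzmc (4.42-fold, 3.85 to 5.09) were also lower on day 21 than on day 14. Hspa1a (4.05-fold, 2.98 to 5.62) and Hist1h2ap (3.39-fold, 2.68 to 4.35) were lower on day 21 than on day 14. Adamts9 (20.7-fold, 10.2 to 48.7) and Csf2 (7.50-fold, 5.42 to 10.6) were also higher on day 60 than on day 21. Tmem176b (5.03-fold, 3.92 to 6.53), Rab4a (6.06-fold, 3.65 to 10.6) and Socs2 (5.57-fold, 3.61 to 8.91) were higher on day 60 than on day 21. Serpinb9b (7.02-fold, 5.27 to 9.51) and Gzmb (5.85-fold, 5.24 to 6.56) were also lower on day 60 than on day 21. Gzma (4.85-fold, 4.57 to 5.15) and Plac8 (4.69-fold, 3.73 to 5.94) were lower on day 60 than on day 21.

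DC-like cells of the day 14 library held higher interferon-gamma (1.64, 25 of 28 higher; Gbp2 8.97-fold (7.34 to 11.1)) and cell cycle genes (1.78; Ube2c 21.1-fold (13 to 36.4)) and lower type I interferon genes (-1.20; Ifit1 lower by 28.8-fold (20.4 to 42.0)) than on day 0. Mature DC-like cells, which carry antigen to lymph nodes, were 1.39% (0.452 to 3.21) of DC-like cells on day 0, 19.7% (15.9 to 23.9) on day 14, 11.1% (8.23 to 14.5) on day 21 and 2.87% (1.83 to 4.27) on day 60. On days 21 and 60 the interferon-gamma list stood at 0.77 and -0.36, type I interferon at -0.60 and -1.08, the cell cycle at 0.26 and 1.09 and HIF-1 targets at 0.59 and 0.33. Ifitm1 was 13.5-fold (11.9 to 15.5), 10.8-fold (9.49 to 12.4) and 9.91-fold (8.72 to 11.3) higher on days 14, 21 and 60. MHC class II genes stood at -0.22, -0.08 and -0.26 (percentiles 7.79, 19.3 and 1.25) and inflammatory genes at -0.95, -0.79 and -0.42, beside stress lists at -1.45, -1.44 and -1.03. AY761185 (at least 256-fold) and AA467197 (117-fold, 63.6 to 245) were also higher on day 14. Pdcd1lg2 (17.8-fold, 13 to 24.9) and Serpinb6b (14.2-fold, 11.9 to 16.9) were higher on day 14. Pmp22 (36.8-fold, 24 to 59.3), Rsad2 (21.7-fold, 15.6 to 31.0) and Apoe (16.4-fold, 15.5 to 17.3) were also lower on day 14. AA467197 (61.0-fold, 33.0 to 128), Serpinb6b (6.28-fold, 5.26 to 7.56) and Plac8 (4.49-fold, 4.01 to 5.03) were also higher on day 21. Cd207 (11.4-fold, 8.79 to 14.9) and Tnfsf9 (8.44-fold, 7.74 to 9.22) were also lower on day 21. Jun (8.04-fold, 7.43 to 8.71) and Retnla (7.59-fold, 7.24 to 7.97) were lower on day 21. Plac8 (4.67-fold, 4.20 to 5.22), Mdh2 (2.26-fold, 2.09 to 2.44) and Fam96a (2.28-fold, 2.02 to 2.57) were also higher on day 60. Hspa1a (5.69-fold, 5.30 to 6.12) and Rsad2 (5.52-fold, 4.74 to 6.43) were also lower on day 60. Ifit1 (5.41-fold, 4.71 to 6.22) and Hspa1b (4.76-fold, 4.22 to 5.37) were lower on day 60. C1qb (5.33-fold, 4.81 to 5.91) and C1qc (5.16-fold, 4.61 to 5.78) were also higher on day 21 than on day 14. C1qa (4.86-fold, 4.38 to 5.4), Hmox1 (4.11-fold, 3.61 to 4.69) and Emp1 (3.75-fold, 3.26 to 4.32) were higher on day 21 than on day 14. AY761185 (4.25-fold, 3.68 to 4.92) and Cxcl9 (3.69-fold, 3.32 to 4.11) were also lower on day 21 than on day 14. Ly6a (2.97-fold, 2.70 to 3.26) and Procr (2.87-fold, 2.63 to 3.13) were lower on day 21 than on day 14. Pf4 (8.74-fold, 6.96 to 11.1) and Retnla (4.48-fold, 4.27 to 4.69) were also higher on day 60 than on day 21. Lyz1 (4.13-fold, 3.91 to 4.37), Sepp1 (3.15-fold, 2.95 to 3.37) and F13a1 (3.39-fold, 2.92 to 3.96) were higher on day 60 than on day 21. AA467197 (14.8-fold, 12.2 to 18.2) and Serpinb9 (4.46-fold, 4.02 to 4.94) were also lower on day 60 than on day 21. Serpinb6b (4.02-fold, 3.64 to 4.45) and Mmp12 (3.71-fold, 3.42 to 4.02) were lower on day 60 than on day 21. C1qa, C1qb, C1qc and Apoe are macrophage markers and F13a1 is a monocyte marker. Cluster 9, which held 65.6%, 55.2%, 64.3% and 64.7% of DC-like cells on days 0, 14, 21 and 60, had a macrophage score of 0.538. The values of these genes, and of Pf4, Sepp1 and Pmp22, were not separated from phagocytes or their RNA within the class.

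T-like cells that shared their receptor with another cell were 4.41% (2.54 to 7.06) of those with a receptor on day 0, 47.7% (44.1 to 51.4) on day 14, 25.9% (23.2 to 28.8) on day 21 and 9.14% (6.30 to 12.7) on day 60 (363, 754, 992 and 339 cells). In 339 cells drawn from each library the shares were 4.08%, 36.6%, 17.8% and 9.14%, and over all receptor barcodes 11.8%, 40.1%, 21.6% and 12.8%. Of CD4 T-like cells, 60.9% (56.2 to 65.5) and 53.7% (47.8 to 59.4) were in expanded clonotypes on days 14 and 21, against 11.1% and 1.75% of CD8 T-like cells, while 20.3% (15.5 to 25.8) of Treg-like cells were in expanded clonotypes on day 21. Of the 161 expanded CD4 T-like cells of day 21, 74 belonged to 1 clonotype. Expanded here means 2 or more cells with 1 clonotype in the library, so it depends on how many cells were read.

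On day 21, 1 clonotype held 79 T-like cells, 7.96% (6.36 to 9.83) of those with a receptor, and the next held 8. Its chains were TRAV5-1 and TRAJ37 with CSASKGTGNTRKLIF and TRBV19 and TRBJ1-6 with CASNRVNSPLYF, and 71 of the 79 cells lay in cluster 26, the CD4 cluster led by Ccl1, Csf2, Il17a and Ifng. The largest clonotype of day 14 held 19 cells, or 2.52% (1.52 to 3.91), and used TRBV13-2 with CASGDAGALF, and those of days 0 and 60 held 2 and 4. The clonotype of 4 cells on day 60 had the invariant alpha chain TRAV11 with TRAJ18 and no beta chain, and the next 3, of 3 cells each, had a beta chain alone. Of the 31 expanded cells of day 60, 23 were gamma-delta T-like, so clonotypes with 1 chain read there are weak evidence of a shared clone. TRBV19 was used by 12.9%, 15.3%, 21.7% and 13.1% of cells on days 0, 14, 21 and 60, and by 12.8%, 15.5%, 11.3% and 13.1% of clonotypes. Treg-like and CD4 T-like cells shared 2 clonotypes on day 14 and 0 in the other libraries.

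B-like and plasma-like cells with a class-switched heavy chain, a mark of a germinal centre or similar response, were 1.17% (0.242 to 3.39) of 256 cells on day 0, 5.45% (1.14 to 15.1) of 55 on day 14, 5.95% (1.96 to 13.3) of 84 on day 21 and 3.47% (1.28 to 7.40) of 173 on day 60. In B-like cells alone the switched shares were 1.20%, 3.70%, 2.78% and 2.27%, and over all receptor barcodes 0.771%, 4.03%, 4.79% and 2.95%. Cells in expanded B cell clonotypes were 11% (7.98 to 14.6), 6.15% (1.70 to 15.0), 15.6% (10.2 to 22.5) and 23.6% (19.3 to 28.3) of 374, 65, 147 and 360 cells with a clonotype. A heavy chain with a named constant gene was read in only 256, 55, 84 and 173 cells. How many of these clonotypes rest on 1 chain was not examined, and equal cell numbers were not drawn for B cells. These shares are therefore weak evidence of shared clones. IGHD was the heavy chain of 25.4%, 1.82% (1 of 55 cells), 7.14% and 2.89% of cells on days 0, 14, 21 and 60, and over all receptor barcodes of 22.9%, 17.7%, 12.6% and 3.32%. The intervals of the switched shares overlap across all 4 libraries.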

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

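The tests on cluster 40 were chosen only after the result was seen. None of the differences between days or between clusters named here was itself tested.

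Cell cycle genes of NK-like cells lay on opposite sides of day 0 in 2 libraries, with a list median of 1.92 on day 14 and -0.78 on day 60. Interferon-gamma response genes of neutrophil-like cells did the same, at 2.72 on day 14 and -1.13 on day 60. These stand out because the same contrast points in opposite directions at 2 time points. The difference between the time points was not tested.

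Several clusters outside the named classes held a larger share of a later library than of the day 0 control. Cluster 4 held 10.5% of the cells on day 14 against 0.217% on day 0, cluster 16 held 4.95% on day 21 against 0.434%, and cluster 11 held 5.55% on day 60 against 1.56%; macrophage was the best score of all 3. Cluster 12, a mix of macrophage and neutrophil markers, held 2.35% on day 21 against 0.521%, and cluster 31, a mix of macrophage and B cell markers, held 2.81% on day 60 against 1.27%. Cluster 40 held 1.42% on day 21 and 0 cells in the other 3 libraries. The differences were not tested. Of the barcodes of clusters 12 and 31 before doublets were removed, 51.3% and 13.9% scored as doublets.

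Cluster 40 (150 cells, day 21) carried genes of developing T cells, with Dntt in 84.0%, Rag1 in 50.7% and Ptcra in 26.7% of its cells, against 0.207%, 0.252% and 0.0459% of phagocyte-like cells (median depths 9726.5 and 11753 UMIs). Each of these genes was found in 0 of 557 CD4 and CD8 T-like cells of day 21 (0 to 0.660%). Cycling T cells of the infiltrate were argued against, since 10.1% (5.66 to 16.4) of its 138 cells with a receptor were in expanded clonotypes against 35.1% (26.4 to 44.6) of 114 in cluster 36, the cycling T-like cluster. Cells of thymus tissue stay open: UMIs of Cd4 together with Cd8a or Cd8b1 were found in 48.0% (39.8 to 56.3) of its cells, with the 50% set as the bound for that source inside the interval, and in 2.15% (1.12 to 3.73) of CD4 and CD8 T-like cells, whose median depth was 5613 UMIs. A candidate source is thymus carried over with the heart, and a CD45 sort would not remove such cells. No biological explanation other than cycling T cells was tested, and as the cluster is in 1 library, the day cannot be separated from the dissection.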

How the results depend on the processing

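The alternatives that count clusters 4, 11, 16 and 27 as phagocyte-like, count cluster 40 as T-like, use the authors' cells or 1 UMI minimum, draw equal cell numbers or leave out the largest clonotype were chosen only after the result was seen. A value counts as moved here when it left the counting interval of the value it was compared with, and for these settings the cause was not tested. No paired analysis was possible because each group holds 1 library and the labels pair none of them.

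Class shares moved in 22 of 88 comparisons. Counting cluster 40 as T-like could not move the shares of days 0, 14 and 60, where that cluster held 0 cells. Clustering each library separately gave 47.2%, 36.7% and 52.8% phagocyte-like cells on days 0, 14 and 21 and 2.18% B-like cells on day 21. Counting clusters 4, 11, 16 and 27 as phagocyte-like gave 71.3%, 61.3%, 59.1% and 56.2%, so day 0 held the highest share under that setting but lay below day 21 when libraries were clustered separately. With 1 UMI minimum, phagocyte-like cells were 72.5% on day 0 and 50.9% on day 60, T-like cells 5.0% and B-like cells 2.34% on day 0, and neutrophil-like cells 0.429%, 14.7% and 5.25% on days 0, 21 and 60. With doublets kept, phagocyte-like cells were 43.3% and 39.2% and neutrophil-like cells 17.9% and 14.7% on days 14 and 21. T-like cells were 11.6% on day 21 with cluster 40 counted in. B-like cells on day 21 were 1.11% under the stricter filter and 1.13% among the authors' cells.

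The interferon-gamma, MHC class II, HIF-1 and resident lists of phagocyte-like cells moved in size and kept their direction. TMM scaling gave 3.09 for interferon-gamma, 0.82 for MHC class II and 2.37 for HIF-1 targets on day 14, 1.02 for MHC class II on day 21, and -2.81, -2.90 and -0.74 for resident genes on days 14, 21 and 60. With the 4 unnamed macrophage clusters counted in, interferon-gamma stood at 2.72 and 1.74, MHC class II at 0.77 (percentile 99.3 among random lists) and 0.97 and HIF-1 targets at 2.09 and 1.47 on days 14 and 21, and resident genes at -3.16, -3.03 and -0.67. Under that setting lysosomal genes stood at -0.38 and -0.08 on days 14 and 21 and cell cycle genes at -0.16 on day 14 (percentiles 1.37, 18.5 and 70.3), against 0.06, 0.25 and 0.08 (percentiles 38.5, 85.3 and 96.5). Percentiles were not computed for the other settings. Members with at least 1 UMI gave 2.12 for interferon-gamma on day 21, and the authors' cells 0.96 for MHC class II on day 21 and -2.91 for resident genes on day 14. The stricter filter moved 0 of 27 list medians.

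In T-like cells, 1 list median reversed its direction: with cluster 40 counted as T-like, Th1 on day 21 stood at -0.042. The same setting gave 0.16 for Th17, 1.87 for Treg and 2.80 for cell cycle genes on day 21. Leaving out the largest clonotype moved 0 of 15 list medians.

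Without thinning, Il17a was found in 33.7%, 11.4% and 17.0% of T-like cells on days 14, 21 and 60, Ifng in 8.57%, 18.3%, 9.12% and 9.33% on days 0, 14, 21 and 60, and Foxp3 in 13.6%, 28.5% and 5.6% on days 14, 21 and 60. Of 12 such shares 10 moved, and a share without thinning cannot lie below the thinned one.

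Shares of expanded T cells moved in 9 of 20 comparisons. Some of the 20 could not move: cluster 40 held 0 cells on days 0, 14 and 60, and the equal draw of day 60 took all of its 339 cells. Over all receptor barcodes they were 11.8%, 40.1%, 21.6% and 12.8%. Grouping cells by the TRB chain alone gave 54.2% and 36.1% on days 14 and 21, equal cell numbers 36.6% and 17.8%, and leaving out the largest clonotype 19.5% on day 21. Under each of these settings day 14 kept the highest share and day 21 the next. The 4 shares of class-switched B cells did not move.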

Other observations

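The tests on spread receptor RNA and on handling were chosen only after the result was seen.

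Gamma-delta T-like cells formed the largest T subset of the day 60 library, and in part of them an alpha or a beta chain was read. Of 244 such cells, 88 had a clonotype, which can rest on 1 chain. An alpha chain with the invariant TRAV11 and TRAJ18 pair of natural killer T cells was read in 22 of the 244. That count did not require a clonotype or a productive chain. In all T-like cells, the invariant pair was found in 9, 4, 29 and 33 cells on days 0, 14, 21 and 60. The name of the cluster rests on marker genes, and its cells were not all without an alpha-beta receptor: 1 clonotype of 2 such cells had both chains on day 60. Few receptors were shared between days: days 14 and 21 shared 3 paired receptors, days 14 and 60 shared 1, days 21 and 60 shared 1, and day 0 shared 0 with any.

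On day 21, 1 clonotype held 79 T-like cells. Receptor RNA of the clone spread over other droplets was argued against: 91.4% (83.0 to 96.5) of its 81 kept barcodes were CD4 T-like, against 17.1% (15.1 to 19.2) of 1322 kept barcodes with other receptors. Of the clone's T-like cells 100% had both chains, so none of the 79 was grouped there with a chain missing. The pairing by the authors' clonotypes fixes that share in advance, so it could not serve as a test of merging for a missing chain. An expanded CD4 T cell clone remains open as a hypothesis, which 1 library cannot separate from a clone of a single mouse.

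Heat shock and dissociation genes were lower than on day 0 in most classes. In 17 of 18 pairs of class and later day the list median lay below 0, which cannot be told apart from the day, because handling, library and day coincide. Inflammatory cytokine genes of phagocyte-like cells, lower on day 60 (-0.52), might follow from clusters 10 and 14, which have heat shock genes among their leading genes. Without these clusters the list median was -0.60, which argues against those clusters as the whole cause. Handling that acted on all cells of the day 0 library stays open, as does the disease phase, which was not tested apart from it.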
